A study of Mus musculus with 18 samples.

How the data were processed

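Dimethylation of lysine 79 of histone H3 (H3K79me2), the mark set by the methyltransferase DOT1L, was mapped by chromatin immunoprecipitation and sequencing in mouse CD4 T cells. Per the labels, 9 libraries were made with the H3K79me2 antibody, 3 each from naive cells, Th1 cells and Th2 cells, and 9 input libraries were made beside them. The inputs carried no peak list of their own and entered no test. Naive cells were sorted directly from the spleens of WT mice by surface markers, as CD44-negative cells. Th1 and Th2 cells came from enriched CD4 T cells of reporter mice that were cultured for 4 days on anti-CD3 and anti-CD28 with IL-2, IL-12 and anti-IL-4 (Th1) or with IL-2, IL-4 and anti-IFNg (Th2). They were then sorted by an IFNg reporter (Th1) or by reporters of IL-4 and IL-13 (Th2). Culture, mouse strain and cell type therefore changed together between naive and polarised cells. The labels did not say whether the 3 libraries of a group came from separate animals, so p-values measure only the spread between libraries, which may be technical.

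The deposited files were broad peak lists, 1 per H3K79me2 library, so that peaks had been called separately in each library. Per the submitters' processing notes, Bowtie2, Picard, SAMtools and MACS2 were used with the mouse build mm10; versions, settings and the use of the inputs in peak calling were not given in the sources used here. For each peak the authors deposited the start and end, a display score, a fold enrichment (a ratio to the caller's background) and −log10 p and −log10 q values. The score was 10 times the −log10 q value, truncated, in the deposited lists. These values belong to the peak within its own list, and they were used only to rank or filter peaks of that list. Read depth was not given in the lists, so depth per library is unknown and no counting interval could be set. A library sequenced more deeply or with less background would yield more covered sequence; the covered length is given for each group for that reason.

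Peaks on chromosomes 1 to 19 and X were used. The gene table had coordinates on GRCm38.p6, the assembly of mm10, and held 21627 protein-coding genes on these chromosomes, of which 3839 (17.8%) overlapped another protein-coding gene. Peaks of broad marks cannot be assigned to 1 of 2 overlapping genes, so the values of such genes are uncertain. Among the genes named these are Ccl3, Ccl4, Ctsw, Cxcr5, Fdft1, Foxm1, Foxp3, Gpm6b, Ifit1, Il12rb2, Inpp4b, Itgae, Jak1, Klf3, Ldlrad4, Nop56, Pfkp, Pip5k1b, Rabgap1l, Rag2, Runx2, Shmt2, Slc16a3, Tcf7, Wdr12 and Zbtb20. The table had no strand, so the planned window at the 5′ end of genes could not be drawn, and the percent of the whole annotated gene covered by the merged peaks of a library was measured in its place. This measure saturates at 0 and 100%, and a long gene reaches 100% only if the domain spans all of it. The genome was also split into 5-kb tiles. Genes and tiles with the same value in all 9 libraries were left out, which left 11597 genes and 84522 tiles. All coordinates are 1-based.

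Percent covered was compared with limma (lmFit and eBayes with a variance trend) in a single fit of the 9 libraries with 6 residual degrees of freedom. A gene or tile was called at a Benjamini-Hochberg adjusted p under 0.05 and a difference of at least 25 percentage points. A mean within 25 points of 0 or 100% could therefore not be called to move further towards it, unless libraries were centred. All adjusted p-values of single genes and tiles come from limma. Its eBayes step draws the variance of each gene towards that of other genes. Genes without any spread between libraries of a group owe their p-values to that borrowed variance. Errors are SD over the 3 libraries of a group unless SE is stated. Tested on simulated data for Th1 against naive cells, with 11597 genes, the fit recovered 84% of 100 genes moved by 30 points and 95% of 100 genes moved by 50 points, with 1 false call. With 84522 tiles it recovered 43.3% and 81.5% of 3000 tiles each, with 51 false calls. Only genes and tiles that started well below full coverage were moved, and only upward. The simulated groups did not differ in covered length. Recovery of losses, and false calls under such a difference, were therefore not tested. Numbers of peaks and covered lengths were compared with 2-sided exact permutation tests, in which 3 libraries against 3 cannot give a p below 0.1. Similarity of libraries was measured with the Jaccard index of covered bases and tested over the 280 ways to part 9 libraries into 3 groups of 3. No pair of libraries shared more than 1 peak with identical coordinates, so each library was counted as its own sample.

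Before the data were examined, 13 gene lists with 238 genes were fixed (Th1 genes, Th2 genes, naive and quiescence, activation, other T helper lineages, cell cycle, glycolysis, amino acid and one-carbon metabolism, sterol and fatty acid synthesis, ribosome biogenesis, interferon response, DOT1L and its partners, and housekeeping), as were 44 cell type markers; 237 of the 238 were in the gene table. Lists were tested with limma's camera (2-sided, inter-gene correlation 0.01, Benjamini-Hochberg over 39 tests), with camera at an estimated correlation and with fry. Camera compares a list with all other genes, and fry asks only whether a list's genes move, on balance, one way. Members were counted as called over all genes and with p-values adjusted over the list alone. Genes named were chosen by a rule fixed at the same time. Per comparison these were the 10 genes per direction with the largest difference in covered kb among called genes whose libraries separated completely, all called members of the Th1 and Th2 lists, Ifng, Tbx21, Il4, Il5, Il13 and Gata3 in any case, and up to 4 called members with the largest differences from each other list. Some genes that this rule took, and some markers, are not reported here, but they remain in all counts and tests.

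Alternatives fixed at the same time were a −log10 q of at least 5; a matched covered length of 217 Mb, in which each library kept its peaks of highest fold until it covered as much as the smallest list; libraries centred to the same mean; merging of peaks closer than 1 kb; the replicate number as a block; other variance, filter, difference and tile settings; a rule without a model; and each library left out in turn. Matched covered length cut the naive lists most. They kept 9203 to 9873 peaks, with lowest folds of 2.80 to 2.92, while the 3rd Th1 list kept all 41504, from 1.64-fold. Against naive cells it therefore favours gains and ends losses by construction. Chosen after seeing the data were the whole gene with 1 kb on each side, a window at the better covered gene end (1 kb outside to 5 kb inside), 2 kb on each side of that end, and a test without overlapping genes. Long noncoding RNA genes at least 5 kb from a protein-coding gene were also tested after the data were seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, bedtools 2.31.1, and R 4.3.3 with limma 3.58.1 were used.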

Results

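H3K79me2, a histone mark laid along the bodies of active genes by DOT1L, was mapped in naive CD4 T cells sorted from mouse spleens and in Th1 and Th2 cells made from CD4 T cells in 4 days of culture. Each cell type had 3 libraries, and each library had its own list of broad peaks on mm10. The series addressed the role of DOT1L in T helper cells, and the design allowed 3 comparisons: Th1 with naive, Th2 with naive, and Th2 with Th1 cells. The lists held 39524 ± 1310 peaks in naive, 43400 ± 2390 in Th1 and 48975 ± 2985 in Th2 cells (SD, n = 3 each). The read depth behind the lists is unknown.

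The naive lists covered more of the genome with fewer and wider peaks. Peaks covered 279.98 ± 4.68 Mb in naive, 226 ± 12.2 Mb in Th1 and 240.3 ± 8.93 Mb in Th2 cells, and the median peak width was 1616 ± 115 bp, 1217 ± 90.1 bp and 1134 ± 101 bp. Domains longer than 10 kb numbered 7072 ± 91.7 in naive, 5661 ± 308 in Th1 and 5773 ± 183 in Th2 cells and held 75.9%, 68.9% and 67.7% of the covered bases. All 3 naive lists covered more than any Th1 or Th2 list, differences of -53.6 Mb for Th1 and -39.6 Mb for Th2 cells (exact permutation p = 0.1 each, adjusted p = 0.15 over 6 tests, the smallest p possible being 0.1). Th1 and Th2 lists differed by 14.0 Mb (exact permutation p = 0.3, adjusted p = 0.3). The naive lists held fewer peaks than the Th1 lists by 3875 (exact permutation p = 0.1, adjusted p = 0.15) and than the Th2 lists by 9451 (exact permutation p = 0.1, adjusted p = 0.15). The Th2 lists held 5576 more than Th1 lists (exact permutation p = 0.2, adjusted p = 0.24). With only peaks of −log10 q of at least 5 the sign of these 3 differences in peak number turned, to -222, -683 and -461, but the naive lists still covered the most, 222 Mb against 173 and 175 Mb.

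**Figure D1:**
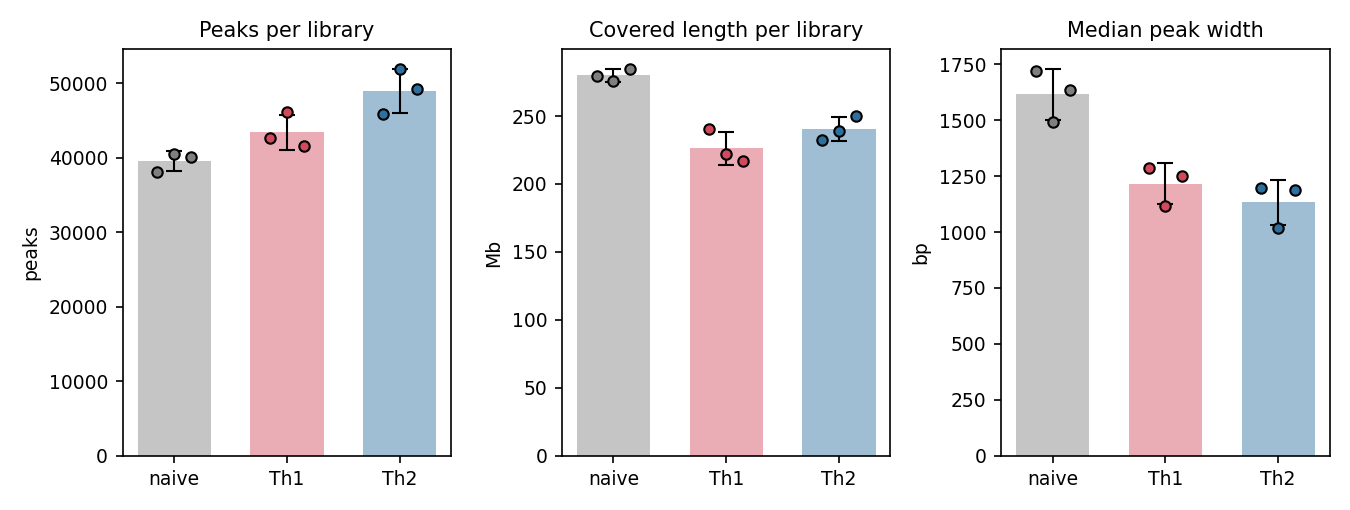
Number of peaks, covered length in Mb and median peak width in bp of each H3K79me2 library by cell type, with points for libraries, bars for group means and lines for SD (n = 3). The 3 naive libraries covered 279.98 ± 4.68 Mb, above all Th1 and Th2 libraries, with the fewest peaks.

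Libraries of a cell type shared more of their covered bases with each other than with other cell types. The mean Jaccard index was 0.867 between naive libraries, 0.829 between Th1 and 0.815 between Th2 libraries. It was 0.754 between Th1 and Th2 libraries, 0.627 between naive and Th1 and 0.641 between naive and Th2 libraries. The real grouping had the largest difference of within-group and between-group means of all 280 possible groupings, 0.163 with the next at 0.125 (exact permutation p = 0.00357, the smallest the design allows).

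Most of the covered sequence lay in genes. Protein-coding genes, which span 39.1% of the chromosomes, held 87.7% ± 0.260 of the covered bases in naive, 87.8% ± 0.586 in Th1 and 85.9% ± 1.33 in Th2 cells. At least 50% of the gene was covered in at least 2 of 3 libraries for 7158 genes in naive, 5729 in Th1 and 5804 in Th2 cells. Of these, 5122 were marked in all 3 cell types, and 1493, 124 and 116 were marked in naive, Th1 or Th2 cells alone. These last counts were 914, 204 and 149 with matched covered length, 493, 174 and 241 when any overlap counted, and 781, 152 and 166 in a window at one gene end. Over the 5122 shared genes the median covered length was 13.8 ± 0.0864 kb in naive, 12.7 ± 0.372 kb in Th1 and 12.6 ± 0.242 kb in Th2 cells. Summed over the peaks within 1 gene, the longest covered lengths were those of Inpp4b, which encodes a phosphoinositide phosphatase, with 642 ± 17.4 kb in naive and 660.1 ± 9.51 kb in Th2 cells, and of Foxp1, which encodes a transcription factor of T cell quiescence, with 588 ± 0.660 kb in naive, 539 ± 5.88 kb in Th1 and 512 ± 4.04 kb in Th2 cells. Lpp followed with 492 ± 17.1 kb, 519 ± 30.1 kb and 504 ± 32.9 kb. Bach2, a repressor that keeps T cells from effector fates, was covered over 346 ± 0.394 kb in Th1 and 347 ± 0.427 kb in Th2 cells, 99.6% and 99.9% of the gene.

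The strongest peaks of each list were ranked by the authors' fold enrichment within that list. Of the genes under the 100 strongest peaks, 77 recurred in all 3 naive, 88 in all 3 Th1 and 75 in all 3 Th2 lists. The 14 shared by all groups included Bcl11b, a T lineage transcription factor, Lck, the kinase of the T cell receptor, and Csk, its inhibitor, beside broadly used genes such as Rac1, Larp1 and Ube2n. Lef1, Tcf7, Jak1 and Smad4 were among 41 genes at the top of naive lists only. Icos, Fyn, Casp8 and 7 genes of the Gimap family were among 17 at the top of Th1 lists only, and Gata3, Il2ra, Stat5a, Stat5b and Pfkp were among 12 at the top of Th2 lists only. Such genes were absent from the 100 strongest peaks of the other groups, not always from their lists. The single strongest peak lay on Ankrd44 in all 3 naive libraries (11.6, 12.5 and 10.9-fold), and on Bcl11b in the 1st and 3rd Th1 libraries (17.99 and 14.1-fold). It lay on Pgam1, a glycolytic enzyme gene, in the 2nd Th1 library (15.9-fold) and all 3 Th2 libraries (15.4, 15.4 and 17.3-fold). These recurrences were not tested.

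Marker genes of the T lineage were covered in every group. Coverage of Cd3e, Thy1 and Lat was 100%, and that of Cd4 was 83.5% ± 1.33 in naive, 83.2% ± 2.76 in Th1 and 81.9% ± 1.88 in Th2 cells; the lowest of the 10 T lineage values was that of Cd4 in Th2 cells. The B cell genes Ms4a1, Pax5 and Blk and the myeloid genes Lyz2, Csf1r, Cd14 and Adgre1 were listed at 0% in all groups, as was Ncr1 of NK cells. Some genes of other cell types were covered, such as Cd79a at 100% everywhere, Cd79b at 54.3% ± 25.9 in naive and 0% in Th1 and Th2 cells, and Tyrobp at 100%, 45.0% ± 9.34 and 93.0% ± 12.2 in naive, Th1 and Th2 cells. Klrk1 was at 26.9% ± 8.50, 99.8% ± 0.264 and 2.60% ± 3.20, and Klf1 was at 0%, 21.7% ± 1.91 and 31.5% ± 12.4. The CD8 genes Cd8a and Cd8b1 were both at 100% in naive cells, at 0% and 9.01% ± 2.47 in Th1 cells and at 7.28% ± 7.42 and 23.3% ± 5.10 in Th2 cells. Of 10 genes of non-haematopoietic tissues, Afp reached 8.74% ± 1.17 in naive cells, and no other value in any group reached 1%.

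Th1 cells were compared with naive cells to find where coverage differed between them. The naive cells came from other mice and were not the cells put into culture. Gains and losses here are thus differences between groups, not steps followed in time. Of 21 tested Th1 genes 17 rose and none fell. Tbx21, the Th1 master regulator, went from 0% in naive to 100% ± 0 in Th1 cells, as did Gzmb, the chemokine gene Ccl3 and Hlx (adjusted p = 5.9e-10, 3.2e-08, 5.9e-10 and 9.6e-05). Ccl3 did not vary within any group and Tbx21 hardly did, so their p-values rest largely on variance borrowed from other genes. Il12rb2, the signalling chain of the IL-12 receptor, rose from 29.3% ± 1.93 to 96.4% ± 1.54, Il18rap from 0% to 87.4% ± 1.65, Runx3 from 40.3% ± 1.72 to 98.9% ± 1.06 and Havcr2, the TIM-3 gene, from 0% to 88.8% ± 7.77. Ifng rose from 0% to 100% (adjusted p = 4.6e-08), but its reporter had been used to sort these cells, so it is no independent result.

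The other Th1 genes that rose were Bhlhe40 to 99.8% ± 0.231, Nkg7 to 100%, Cxcr3 to 90.9% ± 4.90, Ccl4 to 88.9% ± 2.65, Eomes to 47.4% ± 8.08 and Ccl5 to 35.6% ± 1.83, each from 0%, and Ly6c2 from 32.1% ± 3.55 to 100% and Il18r1 from 33.1% ± 4.18 to 77.7% ± 1.89. Beside them rose some genes that NK and cytotoxic T cells also use, Klrd1 and Gzmm being chosen after their values were seen: Klrk1 from 26.9% ± 8.50 to 99.8% ± 0.264 (adjusted p = 3.8e-06), Klrd1 from 19.3% ± 2.03 to 100% ± 0 (adjusted p = 4.5e-08) and Gzmm from 0% to 27.7% ± 13.5 (adjusted p = 0.0044). Others of these kinds did not rise. The NK cell marker Tyrobp fell from 100% to 45.0% ± 9.34 and Ncr1 stayed at 0%. Of the genes taken with Klrd1 and Gzmm, Ctsw stayed at 100% and Itgae went from 33.5% ± 2.13 to 29.6% ± 1.45. The list was higher than other genes (camera, adjusted p = 2.5e-21; adjusted p = 0.0273 with an estimated correlation), and the count was 17 adjusted over the list alone. The count and the list tests kept Ifng, by which these cells had been sorted. Ccl3 and Ccl4 overlap each other and Il12rb2 overlaps another gene, so their values are uncertain. In a window at one gene end Il12rb2 turned to -12.9 points, and the calls of Il18r1 there (9.18 points), of Ly6c2 within 2 kb of a gene end (23.7 points), of Ccl5 with matched covered length (23.2 points) and of Ccl3 at a −log10 q of at least 5 (66.7 points, adjusted p = 0.066) ended.

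Several Th2 genes were also covered in Th1 cells. Il10 rose from 0% to 100%, Il24 from 0% to 93.0% ± 12.0, Maf from 11.1% ± 19.2 to 100%, Nfil3 from 6.20% ± 3.39 to 100% and Il1rl1 from 0.186% ± 0.290 to 30.7% ± 11.5. Il17rb fell from 67.8% ± 15.8 to 0% and Epas1 from 40.4% ± 6.30 to 0.404% ± 0.700. Il4 and Il13 were at 23.0% ± 23.6 and 17.6% ± 23.0 in Th1 cells against 0% in naive cells and were not called (adjusted p = 0.084 and 0.16). Il5 was at 0% in both, and Gata3 was at 59.7% ± 1.87 against 75.3% ± 1.18, below the minimum difference. The list's 5 gains and 2 losses among 19 tested genes (5 and 2 adjusted over the list alone) gave a camera adjusted p of 0.00038, and adjusted p = 0.0932 with an estimated correlation. Without the 2nd Th1 library Il4 and Il13 were called higher, at 34.5 and 26.4 points, and libraries centred to one mean gave 31.2 and 25.8 points, also called; the calls of Epas1 (0 points) and Il1rl1 (24.7 points) ended with matched covered length, and that of Il24 at a −log10 q of at least 5 (66.7 points, adjusted p = 0.066).

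Some genes of activation and metabolism gained the mark in Th1 cells. Of 15 tested activation genes 6 rose and none fell, among them Irf8 from 28.9% ± 7.40 to 93.5% ± 0.917, the IL-2 receptor genes Il2ra from 38.5% ± 0.910 to 91.9% ± 1.42 and Il2rb from 50.3% ± 3.20 to 98.3% ± 1.53, and Tnfrsf9 from 36.5% ± 4.58 to 86.0% ± 1.23. Hk2, the inducible hexokinase, rose from 3.85% ± 1.70 to 92.0% ± 3.28. It led 5 of 19 glycolysis genes that rose, with Slc16a3, a lactate exporter (40.8% ± 10.1 to 100%), Pgk1 (58.6% ± 2.26 to 98.3% ± 1.11) and Hif1a (67.4% ± 1.44 to 100%). Of 19 sterol and fatty acid synthesis genes 4 rose, among them Lss (14.4% ± 4.23 to 63.7% ± 4.02), Sqle (42.2% ± 5.13 to 87.6% ± 4.87) and Sc5d (54.9% ± 5.92 to 92.6% ± 7.11). Asns, the asparagine synthetase gene, rose from 0% to 34.8% ± 3.10 and Shmt2, of one-carbon metabolism, from 50.2% ± 4.68 to 92.3% ± 6.85, the 2 called of 12 amino acid and one-carbon genes. Counts adjusted over each list alone were the same. The camera adjusted p was 1.4e-08 for activation, 5.6e-09 for glycolysis, 2.9e-08 for sterol and 0.00033 for amino acid genes; adjusted p = 0.0217, 0.0353, 0.0217 and 0.119 with an estimated correlation, so the last call was lost. Shmt2 and Slc16a3 overlap other genes, and Shmt2 turned to -7.79 points within 2 kb of a gene end; at a −log10 q of at least 5 the call of Asns ended (20.5 points). The calls of Il2ra (15.3 points), Pgk1 (5.92), Sqle (14.1) and Sc5d (1.20) ended in a window at one gene end, and those of Lss (9.41) and Slc16a3 (24.0) within 2 kb of it.

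Losses in Th1 cells included a few naive T cell genes and genes of other T cell fates. Ccr9, a gut and thymus homing receptor, fell from 100% to 0% and Dapl1 from 65.7% ± 14.1 to 0.678% ± 1.17, and Klf3 fell from 84.0% ± 2.72 to 46.4% ± 6.10. The other 14 of 17 tested naive and quiescence genes were not called (camera, adjusted p = 0.36; fry Down, adjusted p = 3e-07; 0 higher and 3 lower over all genes and adjusted over the list alone). Ccr7, Il7r and Foxo1, at 100% in every library, left no difference to test. Foxp3, the regulator of regulatory T cells, fell from 94.4% ± 5.43 to 12.5% ± 4.99, and Cxcr5 and Ikzf2 also fell. Lrrc32 rose from 4.80% ± 2.80 to 93.9% ± 1.19, Il23r from 0% to 62.8% ± 11.8 and Il21 from 42.0% ± 5.89 to 100%, giving 3 higher and 3 lower of 11 other T helper lineage genes, also adjusted over the list alone (camera, Up, adjusted p = 0.13, median -5.62 points, mean 0.272 points). Beside these naive-high genes, Cd8a, Cd8b1, Cd79b and Tyrobp were also higher in naive lists. The call of Foxp3, which overlaps another gene, ended with matched covered length (-49.1 points, adjusted p = 0.096), and that of Klf3 in a window at one gene end (-24.9 points).

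In the other lists few genes were called in Th1 cells. Among interferon response genes Gbp3 rose from 18.2% ± 2.86 to 88.1% ± 0.776 and Gbp2 from 37.6% ± 6.13 to 64.9% ± 3.47, while Irf7 fell from 100% to 17.6% ± 25.1 and Ifit1 from 100% to 54.5% ± 4.35 (2 higher and 2 lower of 13, camera Up, adjusted p = 0.28, median -3.39 and mean -5.11 points). Of 20 ribosome biogenesis genes Nop56 rose from 73.7% ± 10.4 to 100%, and Nop14 fell from 83.1% ± 11.9 to 32.9% ± 7.02, Wdr12 from 69.0% ± 5.23 to 22.6% ± 4.07 and Polr1a from 64.4% ± 1.55 to 21.2% ± 6.04 (camera Up, adjusted p = 0.079, median -0.964 and mean -2.32 points). Mcm5 rose from 58.7% ± 11.3 to 85.3% ± 5.25, the only call among 22 cell cycle genes (camera Up, adjusted p = 0.12, median -1.18 and mean -0.672 points), and Mki67 was at 100% ± 0 and 99.1% ± 1.52. None of 9 DOT1L and partner genes was called (camera Down, adjusted p = 0.59; fry Down, adjusted p = 0.00092, median -7.72 points), with Dot1l at 100% ± 0 in naive and 92.3% ± 7.90 in Th1 cells, and none of 8 housekeeping genes was (camera Up, adjusted p = 0.30, median 0.499 and mean -3.20 points). Counts adjusted over each list alone were the same. Losses of Nop14 and Polr1a ended with matched covered length (-1.72 and -4.04 points), and Nop14 turned to 12.0 points within 2 kb of a gene end. In a window at one gene end Gbp2 (7.85 points), Ifit1 (-14.9), Nop56 (21.9), Wdr12 (-20.8) and Mcm5 (3.33) were not called. Mcm5 was not called without the 1st Th1 (24.1 points) or the 1st or 2nd naive library (22.9 and 23.8), Gbp2 not without the 2nd naive (24.4), and Nop56 not without the 2nd or 3rd naive library (23.6 and 23.0).

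By covered length, the largest gains in Th1 cells were in long genes that were bare or partly covered in naive cells. Setbp1 (chr18 78750378 to 79110444) went from 0.162 ± 0.281 to 254 ± 11.7 kb, Atxn1 from 143 ± 12.0 to 380 ± 8.55 kb, Kcnq5 from 24.8 ± 3.46 to 251 ± 39.9 kb and Chst11, a chondroitin sulfotransferase gene, from 12.3 ± 0.730 to 209 ± 1.64 kb. Farp1, the G protein gene Gnaq, the adhesion molecule gene Alcam, Srgap3, Enox2 and Gpm6b each gained between 130.5 and 178 kb. The largest losses were in Slc9a9 (chr9 94669557 to 95230453), from 419 ± 7.90 to 35.9 ± 9.07 kb, Zbtb20, from 369 ± 22.6 to 40.4 ± 4.59 kb, Inpp4b, from 642 ± 17.4 to 359 ± 34.0 kb, and Arhgap15, from 486 ± 11.8 to 245 ± 26.2 kb. Ldlrad4, Ttc28, Itpr2, Prkce, Xylt1 and Sntb1 lost between -236 and -195 kb. All 10 gains stayed called with matched covered length and 6 of the 10 losses did not (Arhgap15, Inpp4b, Itpr2, Prkce, Slc9a9 and Zbtb20), Inpp4b turning to 5.08 points. That setting cut the naive lists most, so it does not show that gains were steadier than losses. At a −log10 q of at least 5, 8 gains (not Enox2, at 8.11 points, nor Kcnq5, at 15.5) and 6 losses stayed called, and in a window at one gene end 9 and 3 did. Gpm6b, Zbtb20, Inpp4b and Ldlrad4 overlap other genes.

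Over all genes, 2403 of 11597 were called between Th1 and naive cells, 508 higher and 1895 lower in Th1 cells. The median gene differed by -5.55 points, by -1.31 points with matched covered length and by 2.70 points with centred libraries. With matched covered length the calls split into 819 higher and 1030 lower (44.3% higher in place of 21.1%), and with centred libraries into 736 and 1175 (38.5%). A rule without a model asked for at least 50% in all libraries of a group and under 10% in all of the other. It gave 120 genes higher and 116 lower. Among 5-kb tiles 28610 of 84522 were called, 6492 higher and 22118 lower, and 8946 and 9232 with matched covered length. Of the called genes taken by the naming rule, the 20 largest by covered length had to have separated libraries. In all 54 others every library of one group also lay above every library of the other. They had been called from these same libraries, so their separation is no independent support.

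**Figure D2:**
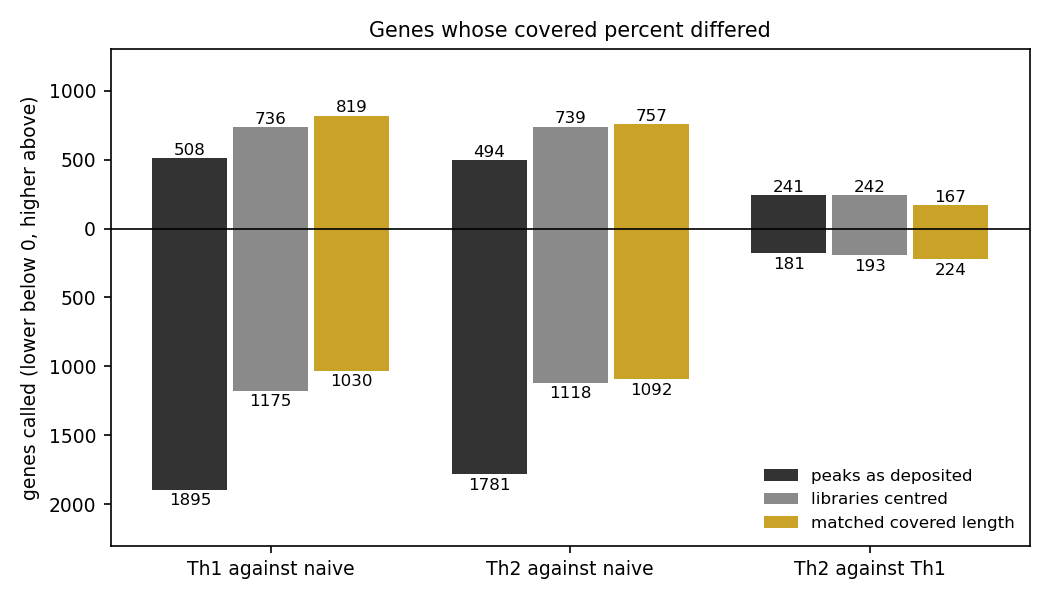
Numbers of genes called higher (up) and lower (down) in each comparison with the lists as deposited, with libraries centred and with matched covered length. The excess of lower genes against naive cells, 1895 to 508 in Th1 cells as deposited, shrank to 1030 to 819 with matched covered length.

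Th2 cells were compared with naive cells in the same fit. The Th2 cytokine locus was bare over its cytokine genes in naive cells and covered end to end in Th2 cells. Il4 and Il13 went from 0% to 100% ± 0 (adjusted p = 8.9e-05 and 7.8e-05), though both had served to sort these cells and are no independent result. Il5, on the far side of Rad50, rose from 0% to 92.8% ± 12.5 (adjusted p = 5.3e-06), and Rad50, which lies between Il13 and Il5 and holds the locus control region, rose from 40.7% ± 1.86 to 98.3% ± 1.93 (adjusted p = 1.2e-06). From Il4 to Il5 (chr11 53612460 to 53725103) peaks covered 21.9% ± 0.712 of the sequence in naive and 98.8% ± 1.03 in Th2 cells. In each Th2 library a single peak ran over Il4 and Il13 into Rad50, and in the 3rd library it spanned Il5 too. The gains of Rad50 and Il5 are thus not separate from those of the sorted genes.

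Other Th2 genes rose as well, Il10 and Il24 from 0% to 100%, Nfil3 from 6.20% ± 3.39 to 100% and Maf from 11.1% ± 19.2 to 100%, whereas Il17rb, a receptor for IL-25, fell from 67.8% ± 15.8 to 0%. Gata3, the Th2 master regulator, was at 97.8% ± 1.89 against 75.3% ± 1.18 in naive cells, a difference of 22.5 points that was below the minimum (adjusted p = 1e-05). Of 19 tested Th2 genes 8 rose and 1 fell, also adjusted over the list alone (camera, adjusted p = 1.7e-09; adjusted p = 0.0217 with an estimated correlation). The count and the list tests kept Il4 and Il13, by which these cells had been sorted, and Il5 and Rad50 of the same locus. They are thus in part set by the sort. Gata3 was called with centred libraries (30.2 points) and within 2 kb of a gene end (100 points), and Rad50 was not called in a window at one gene end (4.93 points) or within 2 kb of it (21.4).

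Th1 genes were partly covered in Th2 cells. Tbx21 rose from 0% to 99.9% ± 0.160 (adjusted p = 6.8e-10), Gzmb to 95.1% ± 4.32, Bhlhe40 to 99.8% ± 0.222, Havcr2 to 84.3% ± 10.1 and Cxcr3 to 61.8% ± 31.8, each from 0%, Runx3 from 40.3% ± 1.72 to 88.9% ± 8.33 and Il12rb2 from 29.3% ± 1.93 to 70.7% ± 3.08. Prf1, the perforin gene, fell from 76.5% ± 0.750 to 7.69% ± 8.58 and Il18r1 from 33.1% ± 4.18 to 2.12% ± 1.91. Ifng was at 2.77% ± 4.80 against 0% and was not called (adjusted p = 0.33). The 7 gains and 2 losses among 21 genes, also adjusted over the list alone, gave a camera adjusted p of 1.6e-07 and adjusted p = 0.126 with an estimated correlation. The calls of Cxcr3 (0 points) and Il18r1 (-18.5 points) ended with matched covered length, and that of Il12rb2 ended in a window at one gene end (0.572 points).

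Some activation and metabolic genes also gained the mark in Th2 cells. Irf8 rose to 86.0% ± 3.94, Tnfrsf9 to 86.7% ± 4.58, Il2rb to 100% and Il2ra to 79.8% ± 0.828, among 6 of 15 activation genes that rose. Hk2 rose to 86.2% ± 0.426, Slc16a3 and Hif1a to 100% and Pgk1 to 94.9% ± 5.35, the 4 called of 19 glycolysis genes. Lss rose to 59.4% ± 2.99, Sqle to 75.8% ± 2.86 and Fdft1 from 70.3% ± 5.84 to 96.1% ± 1.38, among the 4 called of 19 sterol genes, and Asns to 39.8% ± 1.46, Shmt2 to 89.0% ± 6.57 and Psat1 from 45.8% ± 4.60 to 72.2% ± 1.57, the 3 called of 12 amino acid genes. No member of these 4 lists fell, and counts adjusted over each list alone were the same. The camera adjusted p was 1.1e-08, 3.5e-08, 2.3e-07 and 5.9e-05 in that order; adjusted p = 0.0217, 0.0421, 0.0217 and 0.0932 with an estimated correlation, so the call of the amino acid list was lost. Fdft1 was not called without the 2nd Th2 (24.96 points) or 2nd naive library (22.8 points) and Psat1 not without the 1st naive library (24.6 points). Shmt2 turned to -8.39 points within 2 kb of a gene end and, with 1 kb added on each side of the gene, was not called (23.6). In a window at one gene end the calls of Il2ra (15.3 points), Pgk1 (19.5), Sqle (14.1), Fdft1 (35.0) and Psat1 (20.2) ended, as did that of Lss within 2 kb of it (25.5).

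Losses in Th2 cells again included Ccr9, from 100% to 11.4% ± 4.35, and Dapl1, from 65.7% ± 14.1 to 9.66% ± 4.52, 2 of 17 tested naive and quiescence genes, with none higher (camera, adjusted p = 0.17, and 0.042 with matched covered length; fry Down, adjusted p = 2.9e-07). Foxp3 fell from 94.4% ± 5.43 to 32.4% ± 6.37, Ikzf2, which encodes Helios, from 83.0% ± 1.45 to 16.2% ± 4.91, and Bcl6 and Cxcr5, of follicular helper cells, fell too. Lrrc32 rose to 86.9% ± 4.72 and Il21 to 100%, so 2 rose and 4 fell of 11 other lineage genes (camera Up, adjusted p = 0.13, median -0.0405 and mean -4.41 points). Of 13 interferon response genes 4 fell and none rose, among them Irf7 from 100% to 13.03% ± 12.7, Ifit1 from 100% to 52.5% ± 10.6 and Usp18 from 100% to 74.4% ± 6.41 (camera, adjusted p = 0.39; fry Down, adjusted p = 0.00033). Cd8a, Cd8b1 and Cd79b were also higher in the naive lists, as against Th1 cells. The call of Foxp3 ended with matched covered length (-51.4 points, adjusted p = 0.084), and Usp18 was not called without the 3rd Th2 library (-22.0 points) or with centred libraries (-17.9). The call of Ifit1 ended in a window at one gene end (-24.3 points) and that of Ikzf2 within 2 kb of it (-6.39).

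Of 9 DOT1L and partner genes, Kmt2a, the gene of the MLL1 methyltransferase, fell from 84.4% ± 2.01 to 50.9% ± 1.93 and Aff1 from 83.3% ± 2.47 to 50.3% ± 4.00 in Th2 cells, while Dot1l itself was at 94.7% ± 3.11 against 100% ± 0 and not called (camera, adjusted p = 0.99; fry Down, adjusted p = 0.00092). Nop14 fell to 29.6% ± 4.20, Wdr12 to 24.5% ± 5.06 and Polr1a to 22.6% ± 5.36 and Nop56 rose to 100%, among 20 ribosome biogenesis genes; camera gave Up for this list (adjusted p = 0.047; adjusted p = 0.443 with an estimated correlation) although 3 members fell and 1 rose, with a median of 0.771 and a mean of -1.91 points. Ccnb2 fell from 61.2% ± 1.17 to 23.6% ± 0.688 and Foxm1 from 97.5% ± 2.87 to 61.6% ± 7.97, the 2 calls among 22 cell cycle genes (camera Up, adjusted p = 0.39, median -3.69 and mean -3.29 points). None of 8 housekeeping genes was called (camera Up, adjusted p = 0.39, median -0.708 and mean -4.27 points). Counts adjusted over each list alone were the same here and in the lists above. The calls of Aff1 (-16.8 points), Nop14 (-2.28) and Polr1a (-4.73) ended with matched covered length, and that of Kmt2a in a window at one gene end (-4.47) and within 2 kb of it (-5.20). Wdr12 (-8.98) and Nop56 (21.9) were not called in that window; within 2 kb of a gene end Nop14 turned to 17.1 and Ccnb2 to 0.817 points, and Nop56 was not called without the 2nd or 3rd naive library (23.6 and 23.0 points).

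By covered length, Kcnq5 gained the most in Th2 cells, from 24.8 ± 3.46 to 321 ± 10.4 kb. Efna5, which encodes the ephrin-A5 ligand (chr17 62602957 to 62881317), went from 0 to 260.5 ± 1.77 kb, 93.6% of the gene, and Tanc2 (chr11 105589460 to 105929304) from 0.366 ± 0.332 to 208 ± 1.87 kb. Atxn1, Rabgap1l, Setbp1, Farp1, Nfia, Enox2 and Alcam gained between 145 and 250.2 kb. Slc9a9 lost the most, from 419 ± 7.90 to 73.4 ± 14.8 kb, then Zbtb20 to 56.8 ± 9.68 kb and Ttc28 from 234 ± 7.97 to 14.9 ± 6.39 kb. Arpp21, a gene of thymocytes and neurons (chr9 112065091 to 112236288), fell from 148 ± 0.642 to 0.367 ± 0.635 kb, and Sntb1, Fry, Itpr2, Xylt1, Stx8 and Mad1l1 lost between -183 and -148 kb. With matched covered length 9 of the 10 gains stayed called (not Nfia, at 21.2 points, nor without the 3rd Th2 library, at 23.0) but 4 of the 10 losses, Fry, Itpr2, Mad1l1, Slc9a9, Stx8 and Zbtb20 being lost. Here too the naive lists were cut most, which favours gains by construction. At a −log10 q of at least 5, 6 gains and 6 losses stayed called, the gain of Kcnq5 being lost (14.6 points, adjusted p = 0.042) like those of Enox2 and Nfia, while Rabgap1l, which overlaps another gene, turned to -0.797 points. In a window at one gene end 8 gains and 3 losses stayed called.

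Over all genes, 2275 of 11597 were called between Th2 and naive cells, 494 higher and 1781 lower in Th2 cells, with a median difference of -5.50 points (-1.91 with matched covered length and 2.19 with centred libraries). With matched covered length the split was 757 to 1092 (40.9% higher in place of 21.7%), and with centred libraries 739 to 1118 (39.8%). The rule without a model turned the direction for genes, to 111 higher and 64 lower. Of 84522 tiles 27598 were called, 7645 higher and 19953 lower, and 8477 and 8829 with matched covered length. The libraries of the 2 groups separated completely in all 51 called genes that the naming rule took without asking for it, which is again no support independent of the call.

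The changes of Th1 and Th2 cells against naive cells overlapped widely. Both rose in 329 genes, among them Tbx21, Il10, Maf, Hk2, Setbp1 and Alcam, and both fell in 1474, among them Ccr9, Foxp3, Slc9a9 and Zbtb20. Among genes of like coverage and length that were lower in neither comparison, the genes that fell in both had naive peak folds at a median percentile of 22.0 to 22.9. Independent lists would share 21.6 and 291 genes, and 2 simulated unchanged groups set against these naive libraries shared 0.04 and 0.08 on average over 50 simulations. With no changed gene, the simulated Th1 comparison called 0.12 genes higher and 0.26 lower on average. Its overlap was thus bound to be near 0 and is no reference for the overlap of the real calls. The covariance of the differences was 404.9, against 7.40 in simulation (a difference of 397.5), and their correlation across genes was 0.860 against 0.502. The 3 naive libraries could not be split into parts of 2. The spread of these shared controls gave a covariance of at most 8.11 in simulation, which argues against it as a large part of the excess. A difference common to all 3 naive libraries, such as their larger covered length, enters both comparisons and was not simulated. Part of the excess may come from that. The overlaps were 556 higher and 824 lower with matched covered length.

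Th2 cells were compared with Th1 cells, the comparison in which both sides had been cultured and the covered lengths differed by 14.0 Mb. Ifng was at 100% in Th1 and 2.77% ± 4.80 in Th2 cells (adjusted p = 3e-07), and Il4 and Il13 at 23.0% ± 23.6 and 17.6% ± 23.0 in Th1 against 100% in Th2 cells (adjusted p = 0.0021 and 0.0013); these were the genes by which the cells had been sorted. Among genes not used for sorting, Ccl3 fell from 100% in Th1 to 0% in Th2 cells (adjusted p = 4.3e-09), Prf1 from 99.9% ± 0.0999 to 7.69% ± 8.58, Il18rap from 87.4% ± 1.65 to 6.58% ± 5.46 and Hlx from 100% to 13.9% ± 24.2. Il5 rose from 0% in Th1 to 92.8% ± 12.5 in Th2 cells (adjusted p = 3.5e-05), Rad50 from 57.1% ± 4.61 to 98.3% ± 1.93, Epas1 from 0.404% ± 0.700 to 60.1% ± 4.54 and Gata3 from 59.7% ± 1.87 to 97.8% ± 1.89 (adjusted p = 4.7e-06). Il5 and Rad50 are not separate from the sorted genes, however. In each Th2 library a single peak ran over Il4 and Il13 into Rad50, and in the 3rd library it spanned Il5 too.

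Of 21 Th1 genes 11 fell in Th2 relative to Th1 cells and none rose, with Il18r1, Ccl4, Ly6c2, Eomes, Ccl5 and Il12rb2 the others called (camera, adjusted p = 7.8e-14; adjusted p = 0.0514 with an estimated correlation). Tbx21, at 100% ± 0 and 99.9% ± 0.160, was not called (adjusted p = 1). Of 19 Th2 genes 6 rose, and 1 fell, the IL-33 receptor gene Il1rl1 from 30.7% ± 11.5 to 0.472% ± 0.436 (camera, adjusted p = 0.00041; adjusted p = 0.0932 with an estimated correlation). Il10, Maf and Nfil3 were at 100% in both cell types. Counts adjusted over the list alone were the same. These counts and list tests kept Ifng, Il4 and Il13, by which the cells had been sorted, so they are in part set by the sort. Il5 and Rad50, of the same locus as Il4 and Il13, were kept too. The call of Il12rb2 was lost without the 1st Th1 (-24.9 points) or 1st Th2 library (-24.4) and turned to 13.5 points in a window at one gene end. Those of Gata3 (23.3 points) and Rad50 (4.53 points) were lost in that window, those of Ccl5 (-23.2) and Il1rl1 (-24.9) with matched covered length, and that of Ccl3 at a −log10 q of at least 5 (-66.7 points, adjusted p = 0.24).

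**Figure D3:**
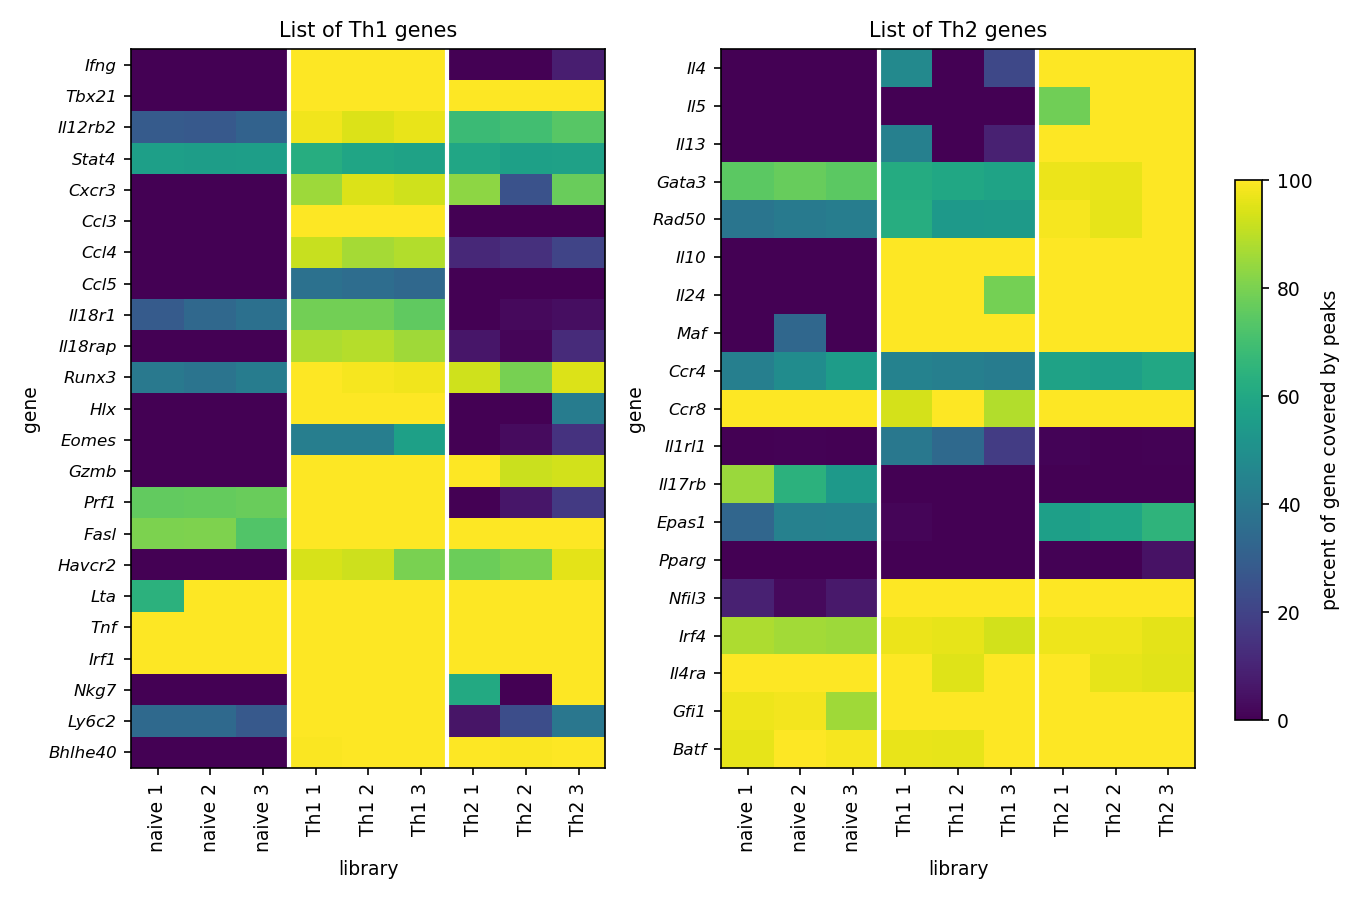
Percent of each gene of the Th1 and Th2 lists covered by H3K79me2 peaks in each of the 9 libraries, for list members covered in at least 1 library. Ifng, Ccl3 and Il18rap were covered in Th1 libraries, Il5 and Rad50 most in Th2 libraries, and Tbx21, Il10 and Maf in both.

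At the Th2 cytokine locus, peaks covered 34.5% ± 5.05 of the sequence from Il4 to Il5 in Th1 and 98.8% ± 1.03 in Th2 cells. Around Ifng, within 100 kb on each side (chr10 118341046 to 118545894), peaks covered 56.3% ± 16.7 in Th1 cells, with single libraries from 37.9 to 70.6%, against 0.0656% ± 0.114 in Th2 and 0% in naive cells. These shares of sequence were not tested.

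**Figure D4:**
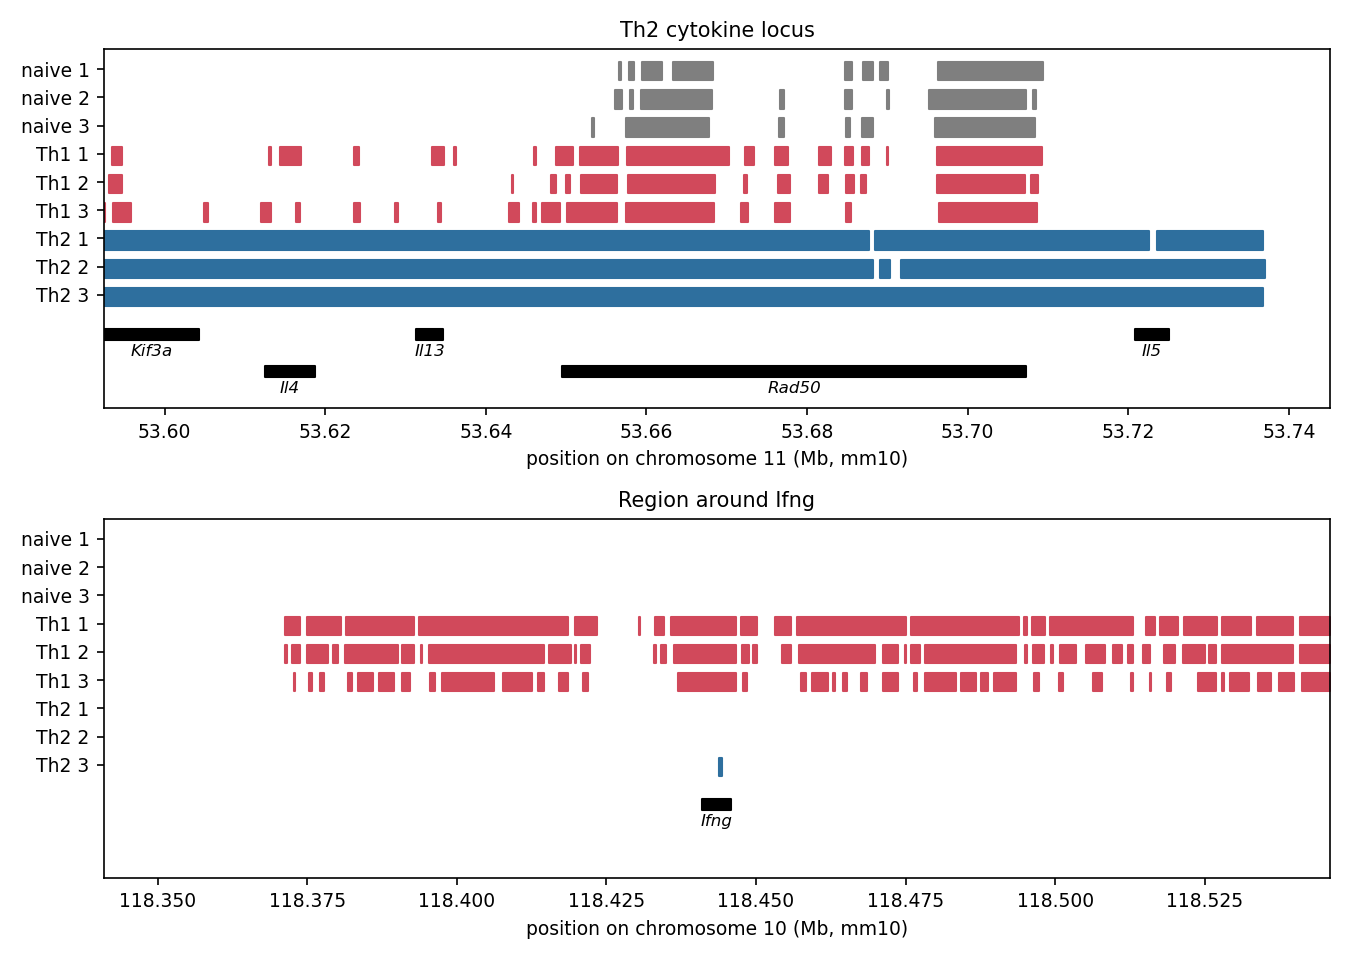
H3K79me2 peaks of the 9 libraries at the Th2 cytokine locus (chr11) and around Ifng (chr10), with positions on mm10 along the axis and protein-coding genes drawn to scale. Peaks filled 98.8% ± 1.03 of the span from Il4 to Il5 in Th2 libraries and 56.3% ± 16.7 of the span around Ifng in Th1 libraries.

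In the other lists 3 or fewer genes each were called between Th2 and Th1 cells. Of 13 interferon response genes 3 fell and none rose, with Gbp3 falling from 88.1% ± 0.776 to 27.6% ± 3.86 and Gbp2 from 64.9% ± 3.47 to 23.5% ± 2.14 (camera, adjusted p = 0.00028; adjusted p = 0.126 with an estimated correlation). Il23r fell from 62.8% ± 11.8 to 13.1% ± 3.91, the only call among 11 other lineage genes (adjusted p = 0.39), and Sc5d from 92.6% ± 7.11 to 64.4% ± 8.06, the only one among 19 sterol genes (adjusted p = 0.095), and not without the 3rd Th1 library (-24.5 points) or in a window at one gene end (0 points). No member was called among naive and quiescence (camera, adjusted p = 0.63), activation (0.27), cell cycle (0.098), glycolysis (0.16), amino acid (0.63), ribosome biogenesis (0.99), DOT1L and partner (0.99) and housekeeping genes (0.57). The naive list had a median of -0.183 and a mean of 0.852 points and camera gave Down; the ribosome list had -0.106 and 0.415 and the DOT1L list 1.01 and -0.434, also Down. The counts were the same adjusted over each list alone. Klrk1, an NK cell receptor gene, was at 99.8% ± 0.264 in Th1 and 2.60% ± 3.20 in Th2 cells, beside the genes that were higher in Th1 cells. Klrd1 was likewise at 100% ± 0 and 7.52% ± 2.60 (adjusted p = 1.1e-07), and Gzmm at 27.7% ± 13.5 and 1.80% ± 3.12 (adjusted p = 0.024). Tyrobp went the other way, at 45.0% ± 9.34 in Th1 and 93.0% ± 12.2 in Th2 cells. Ctsw was at 100% and 99.0% ± 1.67 and Itgae at 29.6% ± 1.45 and 39.2% ± 0.987.

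By covered length, Efna5 and Tanc2 were covered in Th2 cells and hardly elsewhere, with 260.5 ± 1.77 and 208 ± 1.87 kb against 0 and 0.477 ± 0.465 kb in Th1 cells (adjusted p = 4.3e-09 each). Inpp4b and Arhgap15 were longer in Th2 than in Th1 cells by 301 and 255 kb, and Adk, Nfia, Pip5k1b, Fars2, Tiam1 and Ldlrad4 by 115 to 164 kb. Runx2, a Runx family transcription factor gene, was covered over 158 ± 8.04 kb in Th1 and 50.4 ± 7.65 kb in Th2 cells, Eps8 over 128 ± 4.61 and 41.7 ± 31.4 kb and Tmem163 over 119 ± 9.16 and 33.3 ± 26.3 kb. Dock9, 1700025G04Rik, Gnaq, Chst11, Niban1, Ptpre and Dgkh were shorter in Th2 cells by -82.0 to -54.2 kb. With matched covered length 9 of the 10 gains (not Nfia, at 20.6 points) and all 10 losses stayed called, but at a −log10 q of at least 5 only 4 and 8 did. In the window at one gene end 3 gains and 6 losses stayed called, Runx2, Dock9, Gnaq and Niban1 among those lost, and Fars2 turned to -0.367 and Ldlrad4 to -2.04 points. The calls of Eps8 (-39.2 points) and Runx2 (-36.3) ended within 2 kb of a gene end, and those of Nfia and Chst11 were lost without the 3rd (22.3 points) and the 1st Th2 library (-24.1 points).

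Over all genes, 422 of 11597 were called between Th2 and Th1 cells, 241 higher and 181 lower in Th2 cells (57.1% higher), with a median difference of 0.0180 points (-0.394 with matched covered length and -0.531 with centred libraries). The split turned to 167 higher and 224 lower with matched covered length (42.7%), so no overall direction is given. Of 84522 tiles 7395 were called, 4904 higher and 2491 lower, and 3073 and 2918 with matched covered length. In all 23 called genes that the naming rule took without asking for it, the libraries of the 2 groups separated completely. As above, that is not independent of the call.

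Without any model, the merged peaks of all libraries gave 60558 regions over 366 Mb. A region counted as present in a cell type where at least 50% of it was covered in at least 2 of 3 libraries, and 7069 regions were present in all 3 cell types. Present in a single cell type and in no library of the others were 8340 regions in naive, 1624 in Th1 and 3233 in Th2 cells, and 1105 were present in Th1 and Th2 but not in naive cells. The number found only in naive cells fell to 861 with matched covered length, where those only in Th1 and Th2 cells were 2424 and 1596.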

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

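No test in this part was chosen after its result was seen. In 3 genes the mark rose in Th1 cells and fell in Th2 cells, each against naive cells, and the difference between Th2 and Th1 cells was itself called. Il18r1, a chain of the IL-18 receptor (chr1 40465552 to 40500854), was at 33.1% ± 4.18 in naive, 77.7% ± 1.89 in Th1 and 2.12% ± 1.91 in Th2 cells (SD, n = 3), a difference of -75.5 points between Th2 and Th1 cells (adjusted p = 1.5e-06). Iigp1, an interferon-inducible GTPase gene (chr18 60373616 to 60392634), was at 55.7% ± 5.10, 92.7% ± 6.29 and 21.7% ± 2.36, a difference of -71.0 points (adjusted p = 2.2e-05). Rrad, a small GTPase gene (chr8 104628070 to 104631350), was at 59.0% ± 5.82, 99.6% ± 0.704 and 26.1% ± 16.8, a difference of -73.5 points (adjusted p = 0.00068). No gene went the opposite way. The fall of Il18r1 in Th2 cells was not called with matched covered length (-18.5 points), with centred libraries (-23.2) or at a −log10 q of at least 5 (-19.9).

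Every comparison was repeated on the 10 ways to split its 6 libraries into 3 and 3, and in each case 1 split, the real one, gave a count as large as the real count. For genes the real count and the highest of the other splits were 2403 and 1 for Th1 against naive cells, 2275 and 0 for Th2 against naive cells and 422 and 1 for Th2 against Th1 cells. For tiles they were 28610 and 0, 27598 and 0, and 7395 and 37. With 10 splits no share under 0.05 can be reached. Each other split mixes libraries of both groups, which shrinks a real difference and adds it to the spread. Low counts in those splits are thus no rate of false calls.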

How the results depend on the processing

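The windows at gene ends, the whole gene with 1 kb on each side and the test without overlapping genes were chosen after seeing the data, and the other settings before. The 37 results gave 426 values under alternative settings, of which 331 were counted as the same and 95 were not. The cause was not tested unless stated. Same meant within 1.5 times for counts and within 1 SD for peak location and domain length. For peak number and covered length it meant the same sign, and for library similarity an exact permutation p under 0.05. The 9 values of library similarity with 1 library left out were counted as the same without a test. Unknown read depth limits all counts, since a library with more reads yields longer peaks. The whole gene from 1 kb upstream of its start and the 2 kb around the gene start were not run, because the gene table has no strand, and the whole gene became the measure itself.

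At a −log10 q of at least 5 the difference in peak number turned to -222 for Th1 against naive (exact permutation p = 0.8), -683 for Th2 against naive (0.1) and -461 for Th2 against Th1 cells (0.7). Protein-coding genes then held 89.3, 89.4 and 88.8% of the covered bases in naive, Th1 and Th2 cells, and the median domain length was 13.2, 11.5 and 11.2 kb. Regions in a single cell type numbered 1760, 307 and 237, and those in Th1 and Th2 but not naive cells 442. Called higher in Th2 than in Th1 cells were 144 genes, and tiles called numbered 15931, 16210 and 3322 for Th1 against naive, Th2 against naive and Th2 against Th1 cells.

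With matched covered length the median domain length was 13.1 kb in naive and 12.1 kb in Th2 cells. Regions only in naive cells were 861, only in Th2 cells 1596, and in Th1 and Th2 but not naive cells 1856. Genes called were 819 higher and 1030 lower in Th1 and 757 higher and 1092 lower in Th2 against naive cells, with 556 higher and 824 lower in both, and tiles called were 18178 and 17306. Centred libraries gave 1175 genes lower in Th1 and 1118 lower in Th2 than in naive cells.

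Regions counted with any overlap were 13401 in all groups and 2362 in Th1 and Th2 but not naive cells. With at least 80% of the region they were 2526 in all groups, 838 only in Th1, 1308 only in Th2 and 509 in Th1 and Th2 but not naive cells. With 3 of 3 libraries needed they were 4128 only in naive, 483 only in Th1, 907 only in Th2 and 552 in Th1 and Th2 but not naive cells. Marked genes were 10909, 10805 and 10993 in naive, Th1 and Th2 cells and 10103 in all with any overlap. With at least 80% covered they were 4216, 3079 and 3060, and 2458 in all. In the window at a gene end they were 8713 in Th2 cells and 7894 in all.

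Without a minimum difference 6920 genes were called in Th1 (1369 higher, 5551 lower) and 6908 in Th2 against naive cells (1405 higher, 5503 lower), and 1762 in Th2 against Th1 cells (1000 higher, 762 lower). With at least 50 points these were 646 (216, 430), 549 (207, 342) and 115 (65, 50), and tiles 16334, 14916 and 3537. The rule without a model gave 236 genes (120, 116), 175 (111, 64) and 41 (20, 21), and tiles 6813, 5550 and 1076. For genes in Th2 against naive cells the direction turned. These settings ask for less or more by construction. Tiles of 2 kb gave 54758, 52170 and 12725 calls and tiles of 10 kb 15068, 14394 and 4170, since their number differs. Within 2 kb of a gene end 786 genes were higher in Th1 and 863 in Th2 than in naive cells.

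Of the 39 tests of gene lists 8 were called with an estimated correlation and 26 with fry, against 16 as reported. Called by fry and not by camera were, against naive cells, the naive, the other lineage and the DOT1L lists in both cell types (adjusted p from 2.9e-07 to 0.0027) and the cell cycle (Down, 0.021) and interferon lists (Down, 0.00033) in Th2 cells. In Th2 against Th1 cells these were the activation (Down, 0.023), cell cycle (Down, 0.037) and sterol lists (Down, 0.024). Fry sets no list against other genes, whose median difference from naive cells was -5.55 and -5.50 points.

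Of 195 results of named genes 166 were the same with matched covered length, where 28 lost their call, and of 191 tested at a −log10 q of at least 5, 153 were the same and 37 lost their call. In the window at a gene end 129 of 188 were the same and 55 lost their call, and within 2 kb of a gene end 138 and 35 of 180.0. Directions turned for Inpp4b in Th1 against naive cells with matched covered length (5.08 points) and for Rabgap1l in Th2 against naive cells at a −log10 q of at least 5 (-0.797). Within 2 kb of a gene end they turned for Nop14 (12.0 in Th1 and 17.1 in Th2 against naive cells), Shmt2 (-7.79 and -8.39), Ccnb2 in Th2 against naive cells (0.817) and Fars2 in Th2 against Th1 cells (-0.55). In the window at a gene end they turned for Il12rb2 in Th1 against naive cells (-12.9) and, in Th2 against Th1 cells, for Il12rb2 (13.5), Fars2 (-0.367) and Ldlrad4 (-2.04).

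With each library left out in turn, 2327 to 2559 genes were called in Th1 against naive cells (479 to 536 higher, 1806 to 2080 lower), 2183 to 2351 in Th2 against naive cells (470.0 to 512 higher, 1671 to 1840.0 lower) and 398 to 424 in Th2 against Th1 cells. Tiles ranged from 26286 to 28357, from 25160 to 27311 and from 6172 to 7324, and the difference of Jaccard means from 0.142 to 0.177. None of these numbers of calls moved by more than 1.5 times. The covered length of Th1 against naive lists ranged from -60.5 to -49.0 Mb and that of Th2 against naive lists from -44.4 to -35.6 Mb. The difference in peak number ranged from 2533 (without the 2nd Th1 library) to 4823 for Th1 against naive, from 8012 to 10992 for Th2 against naive and from 4136 to 7116 for Th2 against Th1 lists, and that in covered length between Th2 and Th1 lists from 9.23 (without the 3rd Th2 library) to 20.9 Mb; neither had been past a threshold.

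The replicate number as a replicate block gave 2383, 2261 and 393 genes and 27630, 26547 and 6260 tiles, in the same order, and changed no call of a gene list or named gene. Libraries with the same number did not deviate together in coverage (correlations from -0.0744 to 0.00149 over 9 pairs, against -0.0262 to 0.0697 over 18 pairs with different numbers). Percent covered saturates and each group has few libraries, so these correlations cannot decide whether equal numbers mark a shared animal, culture or day.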

Other observations

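The tests of noncoding genes, of matched covered length and of domains near the calling threshold as a cause, of Th1 cells within the Th2 sort and of a domain that spreads from a neighbouring gene were chosen after their results were seen; the test of a thymocyte share was added after the coverage of Rag1 was known, and the folds of the other genes were set beside it after they were seen. Of 1158 long noncoding RNA genes at least 5 kb from a protein-coding gene, 258 were called in Th1 against naive cells (110 higher, 148 lower), 267 in Th2 against naive cells (138 higher, 129 lower) and 97 in Th2 against Th1 cells (62 higher, 35 lower). Ifngas1, the noncoding gene beside Ifng (chr10 118502035 to 118556525), was at 73.0% ± 17.4 in Th1 cells and at 0% in naive and Th2 cells (SD, n = 3; adjusted p = 0.0002 against naive and 0.00084 for Th2 against Th1 cells). Trp53cor1, a p53-induced RNA gene, rose from 0% in naive to 98.4% ± 2.73 in Th1 and 100% in Th2 cells. Morrbid, a regulator of myeloid cell survival, rose from 5.28% ± 0.711 to 85.8% ± 2.07 and 75.8% ± 6.44. Mirc35hg rose from 0% to 85.6% ± 1.301 in Th1 and 53.3% ± 5.15 in Th2 cells, and AA388235 fell from 99.0% ± 1.79 to 24.1% ± 2.27 and 33.4% ± 10.98.

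Genes of the double-positive thymocyte, the stage before CD4 and CD8 T cells part, were covered in naive cells and were chosen for description after Cd8a and Cd8b1 had been seen. Rag1 (chr2 101638252 to 101649532) and Rag2, the recombinase genes of T cell receptor rearrangement, were at 100% ± 0 in naive and 0% in Th1 and Th2 cells (adjusted p = 5.9e-10 against Th1 cells for each, Rag2 overlapping another gene). Neither varied within any group, so this p-value rests on variance borrowed from other genes. Ptcra, the pre-T cell receptor chain, was at 92.9% ± 12.3 and 0%, and Dntt, the terminal transferase, at 87.1% ± 3.09 in naive, 28.7% ± 1.61 in Th1 and 27.4% ± 4.15 in Th2 cells. Arpp21, also used by thymocytes, was at 86.3% ± 0.375, 0% and 0.214% ± 0.371. Rag1 and Rag2 stayed at 100% in naive cells with matched covered length, while Dntt was at 63.6% ± 29.5, Arpp21 at 33.0% ± 6.63 and Ptcra at 22.4% ± 38.8, covered in 1 library.

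Cd8a and Cd8b1 were covered in all 3 naive lists although the cells had been sorted as CD4 T cells, from spleens and not from the thymus. CD8 T cells as the main source predicted that at least 3 of 4 other CD8 T cell genes reach 50% in naive cells. Only 1 did (Ctsw, at 100% there and in Th1 cells too), with Itgae at 33.5% ± 2.13, Klrd1 at 19.3% ± 2.03 and Gzmm at 0%. The prediction thus failed, but the level of the mark on these genes in pure CD8 T cells is not known. Ctsw was covered in all groups, so it cannot tell CD8 T cells apart. The test therefore cannot decide. A small share of thymocytes cannot be told apart from the cells' own mark: the fold above background at Rag1, at least 0.635 of that at Cd4, was over the bound of 0.5 set beforehand against it, but Rag2 (0.416 to 0.432) and Ptcra (0.260 to 0.363) were under it, Dntt (0.478 to 0.608) lay on both sides, and the level in pure thymocytes is not known. A small share of CD8 T cells cannot be told apart either, with the excess at Cd8a at 0.396 to 0.452 of that at Cd4, between the bounds, and that at Cd8b1 at 0.560 to 0.606, above both; nor can a domain that spreads from a neighbouring gene, as no single peak lay over both (0 of 3 lists) and gaps of 4.68 to 7.08 kb parted Cd8a from Rmnd5a, but the gaps towards Gm1070 were of 2.24 to 3.46 kb. All 4 of 4 genes of the double-positive stage reached 50%, so a mark kept from the double-positive thymocyte stage may be the source, as may thymocytes in the sort; these are hypotheses found and tested on the same lists.

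More genes lost than gained coverage in both Th1 and Th2 cells against naive cells, and the naive lists covered the most. The rule without a model showed no such excess for genes, with 120 higher and 116 lower in Th1 and 111 and 64 in Th2 cells. For tiles it kept more losses, with 2192 higher and 4621 lower in Th1 and 2408 and 3142 in Th2 cells. With matched covered length the share of lower genes among calls went from 78.9 to 55.7% in Th1 and from 78.3 to 59.1% in Th2 cells, and that of lower tiles from 77.3 to 50.8% and from 72.3 to 51.0%. A larger amount called in the naive lists as the whole cause cannot be told apart from a real excess of losses, because equal covered lengths bring gains and losses close to balance by construction, and 50.8 and 54.1% of the lower genes stayed called lower. Domains near the calling threshold may account for part of the losses: ranked by naive fold among genes lower in neither comparison, of coverage within 10 points and length within 1.5 times, the genes lower in both lay at a median percentile of 22.0 to 22.9 in the 3 naive lists, which a lower level of the mark in naive cells would give too; a ranking among all genes with a peak, set beforehand, gave 42.5 to 43.8 but decides nothing, as a gene must be well covered in naive cells to lose 25 points. Culture and mouse strain changed with the cell type, depth is unknown, and no biological explanation was tested.

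Tbx21 was covered in Th2 cells as in Th1 cells, at 99.9% ± 0.160. Th1 cells within the Th2 sort were argued against, since Ifng and Ccl3, both at 100% in Th1 cells, were at 2.77% ± 4.80 and 0% in Th2 cells. A domain that spreads from a neighbouring gene cannot be told apart from a mark of Tbx21 itself, since a single peak lay over Tbx21 and Tbkbp1 in 1 of 3 Th2 lists and gaps of 1.61 and 2.46 kb parted them in the others. Tbkbp1 was at 100% in Th1 and Th2 and 4.75% ± 8.22 in naive cells, and Osbpl7 on the other side at 23.8% ± 4.87 in Th2 cells. The mark on Tbx21 in both cultured cell types may be its own or part of a domain shared with Tbkbp1. Both genes were bare or nearly so in naive cells, so the lists do not show from which gene such a domain would spread. These are hypotheses that were not tested against transcription.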
